A study of Homo sapiens with 14 samples.

How the data were processed

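Total RNA of 293FT cells was sequenced in 14 libraries. Per the labels' protocols, cells were sorted by fluorescence, keeping the top 15%, 40 h after transfection, ribosomal and globin RNA was depleted, and stranded libraries were read as pairs of 150 bases. All titles carry the name hRNF2, read here as the target. Groups were taken from the treatment labels and replicate numbers from the titles. PE3 replicate 1 was not analysed here. Read alignment with BWA 0.7.17 and the builds GRCh38 and hg38 are named in the submitters' processing notes without their order or role; the caller of sites and its filters are not given in the sources used here.

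The authors deposited a list of called sites per library, without a header. Its whole-number columns were read as deposited counts of reads: the reads covering the site, the reads with each base and the mutated reads. Other columns hold, as deposited, the fraction of covering reads with each base and the edited fraction of the site. A further deposited signal column equals a larger read depth of the site divided by a constant per library, which was read here as mapped bases in gigabases (Gb). That reading is an inference from the values, since the ratio was the same at every site of a library. In the values of the files every site has at least 2 mutated reads, an edited fraction from 5.02% up and from 3.01 reads up per Gb of mapped bases. A site missing from a list was either unedited, uncovered or under these limits, so absence is not a level of 0.

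The order of the base columns was settled from the data. With the bases read as A, C, G and T on the plus strand, the strand of every site followed from the edited fraction, and 17541 of 17541 exonic sites had the same reference base as the transcript sequence of GENCODE release 29 (GRCh38), which also checked the build. A gene was found on the recovered strand for 96.3% of sites, and 19 sites had a gene on the opposite strand only. How the authors assigned strands is not given in the sources used here, so sites where genes overlap on opposite strands carry that uncertainty. Each site took its region from the basic GENCODE transcripts on its strand, in the order coding, 3' UTR, 5' UTR, non-coding exon, intron, with protein-coding genes and the longest transcript first; stop codons count as 3' UTR in this annotation. Protein changes are numbered in that transcript and written in single-letter code with X for a stop. Bases around a site come from the spliced transcript, so context was read for exonic sites only. C-to-T changes are written C-to-U and A-to-G changes A-to-I.

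Because the counts are reads behind called sites and not reads per gene, groups were compared on values per library. Numbers of sites were compared as log2(sites + 1), so folds are on that scale, and shares and levels as percent. Tests were two-sided exact permutation tests of the difference in means over all assignments of the libraries, 220 for 3 against 9, 55 for 2 against 9, 20 for 3 against 3 and 10 for 2 against 3, with Benjamini-Hochberg adjustment over the 23 comparisons, the 24 tests of single changes, the regions or the lists, at 0.05. The 95% intervals hold the shifts that the exact test does not reject. The level at shared A-to-I sites is the mean edited fraction over the 138 sites called in all 14 libraries. Recurrent sites are those called with the same change in all libraries of a group and in no library of another group. The 20 gene lists (reported APOBEC3A RNA targets, ADAR recoding targets, ribosomal proteins, translation factors, splicing factors, chaperones, DNA repair, oncogenes, tumour suppressors, Polycomb, glycolysis, cell cycle, histones, mitochondrial genome, nuclear oxidative phosphorylation, proteasome, cytoskeleton, interferon response, blood cell markers and fibroblast markers) were written from general knowledge. Their genes with a recurrent site were compared by Fisher's exact test with the 5608 genes that had any called site. Lists, designs, alternatives and the rule for named genes were fixed before the data were examined.

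Named genes followed that rule: the 10 genes with the most recurrent hA3A-BE3 sites, the 10 recurrent sites with the highest mean level at most 1 per gene, up to 3 genes per list, up to 5 sites private to PE3 and up to 3 to each control group, up to 5 ADAR recoding targets by the number of libraries with a site, and RNF2. SON was added after its values were seen, since it tied with CDK13 and COG3, as were the PE3 site in TSNAX and the further one in LINC02001. Some genes that the rule names are not reported here.

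Alternatives were stricter limits on covering reads (20 and 50), edited fraction (10%) and mutated reads (5), leaving out sites edited at 90% or more, sites of non-transfected cells or mitochondrial sites, the strand of the annotated gene, scaling to 1000 A-to-I sites or 1000 sites of the other changes, a linear scale, a replicate block and leaving out each library. Scaling to mapped bases and the adjusted p under each alternative were added after the data were seen; comparisons that an alternative leaves as they are entered the adjustment with their main p.

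Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. For hA3A-BE3 against controls, 4.4% of 500 simulated comparisons with no difference and 97.8% of 500 with a 1.5-fold difference had p under 0.05, drawn as Poisson numbers at the mean of the controls. For PE3 against controls these were 4.2% and 85.4%, and 29.8% at 1.25-fold. The simulated libraries had Poisson spread only and no differences in depth. These shares may therefore not hold for the real groups, such as PE3, where replicate 2 had 3.26 Gb of mapped bases.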

Results

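RNA was sequenced from 14 libraries of 293FT cells, a human embryonic kidney line that carries the SV40 large T antigen, to ask whether a prime editor changes bases in cellular RNA away from its target. Prime editor PE3 joins a Cas9 nickase to a reverse transcriptase and writes an edit templated by its guide RNA, with a further guide that nicks the other strand. It was given to 2 of the libraries analysed here. The comparator hA3A-BE3, in 3 libraries, is a cytosine base editor in which a Cas9 nickase carries human APOBEC3A, a deaminase that acts on single-stranded DNA and on RNA. Controls were 3 libraries each of non-transfected cells, cells given EGFP and cells given Cas9, pooled as 9 control libraries. Each library came with a list of called RNA sites, 46372 calls at 22358 distinct sites in all. Between 3.26 Gb of mapped bases (PE3 replicate 2) and 10.64 Gb (Cas9 replicate 3) stood behind a list, as read from the constant ratio of its depth columns, and the median site was covered by 11 to 44 reads. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

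Cells given hA3A-BE3 carried far more C-to-U sites in their RNA than control cells did, in every library. The 3 hA3A-BE3 libraries held 2499, 5113 and 6446 C-to-U sites, a mean of 4686 ± 2008 (SD, n = 3). The 9 control libraries held 42 to 53, a mean of 46.0 ± 3.20 (SD, n = 9). The log2 difference was 6.54, a 92.8-fold excess with a 95% interval of 54.6 to 139, and every hA3A-BE3 library lay above every control (two-sided exact permutation p = 0.00909, the smallest that 3 against 9 can give, Benjamini-Hochberg adjusted p = 0.0418 over 23 comparisons). Under 25 alternatives the exact permutation p stayed between 0.00909 and 0.0364, while the adjusted p ran from 0.0418 to 0.167 and was under 0.05 in 11. C-to-U changes made up 64.1% ± 9.32 (SD, n = 3) of the called sites of hA3A-BE3 cells and 2.01% ± 0.463 (SD, n = 9) of those of controls (exact permutation p = 0.00909, adjusted p = 0.0418). Against each control group alone the excess was 96.1-fold over non-transfected cells, 92.0-fold over EGFP and 90.3-fold over Cas9, and 3 against 3 libraries cannot give an exact permutation p under 0.1, which is what each comparison gave.

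**Figure D1:**
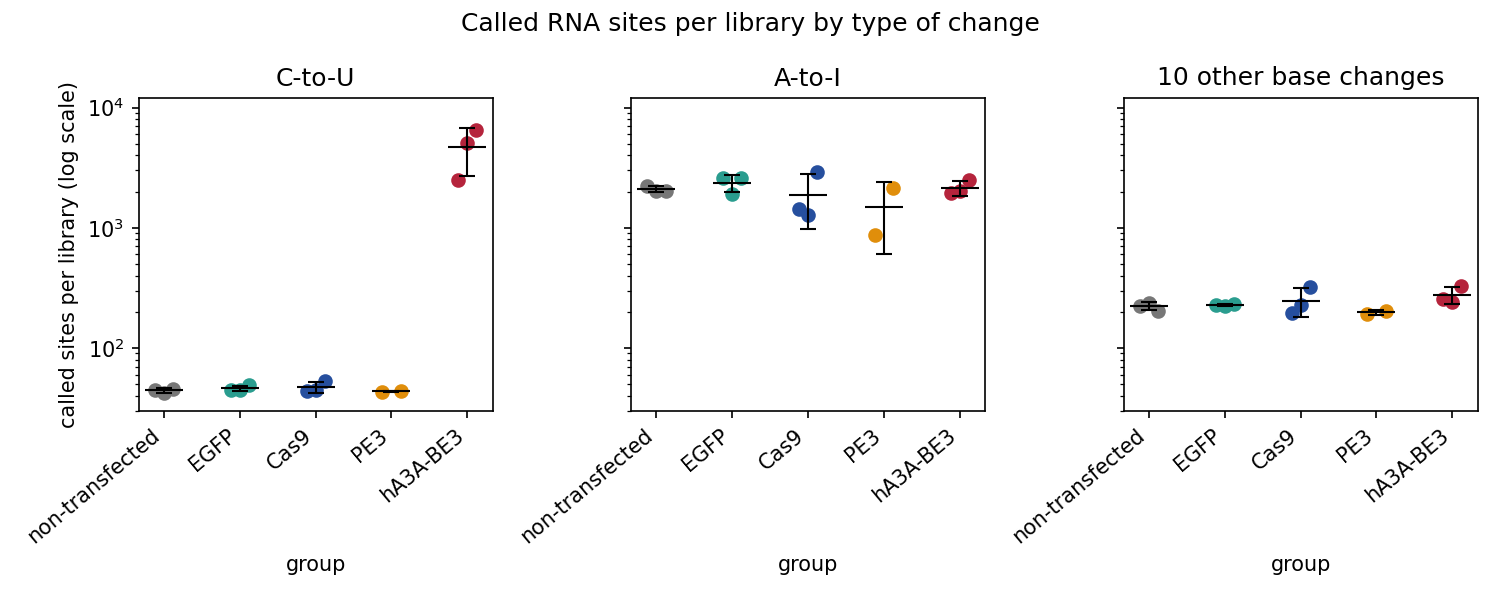
Called sites per library on a log axis for C-to-U, A-to-I and the 10 other base changes, with a point per library and a black bar for the group mean ± SD. The C-to-U sites of the 3 hA3A-BE3 libraries lie between 2499 and 6446, those of the 11 other libraries between 42 and 53, and the A-to-I sites of all 5 groups overlap.

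Many of the hA3A-BE3 sites recurred: 1057 C-to-U sites were called in all 3 hA3A-BE3 libraries and in no library of another group, and 1049 of them lay on the strand of an annotated gene, in 879 genes. Such recurrent sites numbered 0 in the non-transfected, EGFP, Cas9 and PE3 groups, where C-to-U sites shared by a pair of libraries and absent from the other groups numbered at most 2. With a hA3A-BE3 library left out, a site has to be called in fewer libraries, so the number of recurrent hA3A-BE3 sites cannot fall. It ran from 1221 to 2103, the highest without replicate 1, the library with the fewest C-to-U sites. PRRC2B held the most recurrent sites, 5, followed by SESN2, a stress-induced regulator of TOR signalling, the HSP40 co-chaperone DNAJB1 and the splicing factor SF3A1 with 4 each. Of the genes with 3 each, ZNF594, DDOST, CDC5L, DDB1, FASN and IRAK1 had the highest mean levels over their sites, and FLNA, RFC2, PRKDC and MCM6 were among the others. In PRRC2B the sites ranged from I1840I at 10.2% ± 3.70 to S2153L at 26.2% ± 12.3 (SD, n = 3). In SESN2 a 5' UTR site reached 28.97% ± 9.70, a coding site, F321F, 18.6% ± 9.49, and the pair in the 3' UTR 20.5% ± 5.39 and 27.8% ± 8.15 (SD, n = 3). The sites of CDC5L, a spliceosome component, all lay in its 3' UTR, at 19.3% ± 3.09 to 28.6% ± 6.34. The 3 sites of FASN, the fatty acid synthase, were synonymous changes of isoleucine codons, led by I834I at 35.5% ± 9.45. DDB1, a DNA damage-binding subunit, was led by I1130I at 37.8% ± 5.79, and IRAK1, a kinase of Toll-like receptor signalling, by a 3' UTR site at 28.5% ± 8.85 (SD, n = 3).

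The highest level was found in DDOST, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum. On chromosome 1, position 20655484 (GRCh38, minus strand, coding exon), 85.2% ± 2.92 (SD, n = 3) of the reads carried U, from 190 to 292 covering reads per library. The change was synonymous, I186I, within the transcript sequence ACCAUCGUUGG, whose middle base is the edited C. DDOST also carried R198X, a stop codon, at 21.9% ± 7.19 and S103L at 10.5% ± 2.21. In GAPDH, a glycolytic enzyme, I120I (chromosome 12, position 6537133, plus strand, GUCAUCAUCUC) reached 71.9% ± 7.66 over 803 to 1075 reads. The transcription termination factor TTF2 followed with I1039I at 67.4% ± 16.5, and PIGX, which acts in the synthesis of membrane anchors for proteins, with H153Y at 65.8% ± 4.96. THOC5, a part of an mRNA export complex, carried R683C at 62.2% ± 3.85. GSS, which makes glutathione, carried I351I at 60.6% ± 4.99, and the adrenergic receptor gene ADRA2C carried I172I at 60.4% ± 17.2. CYFIP1, a regulator of actin assembly, carried I1074I at 59.7% ± 14.9, the filamin FLNC I608I at 58.7% ± 13.9 and TMEM131 S1217L at 58.4% ± 4.12 (SD, n = 3 throughout). Among all 1057 recurrent sites the median of the mean levels was 13.9%, 290 sites (27.4%) lay at 20% or more and 20 (1.89%) at 50% or more.

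**Figure D2:**
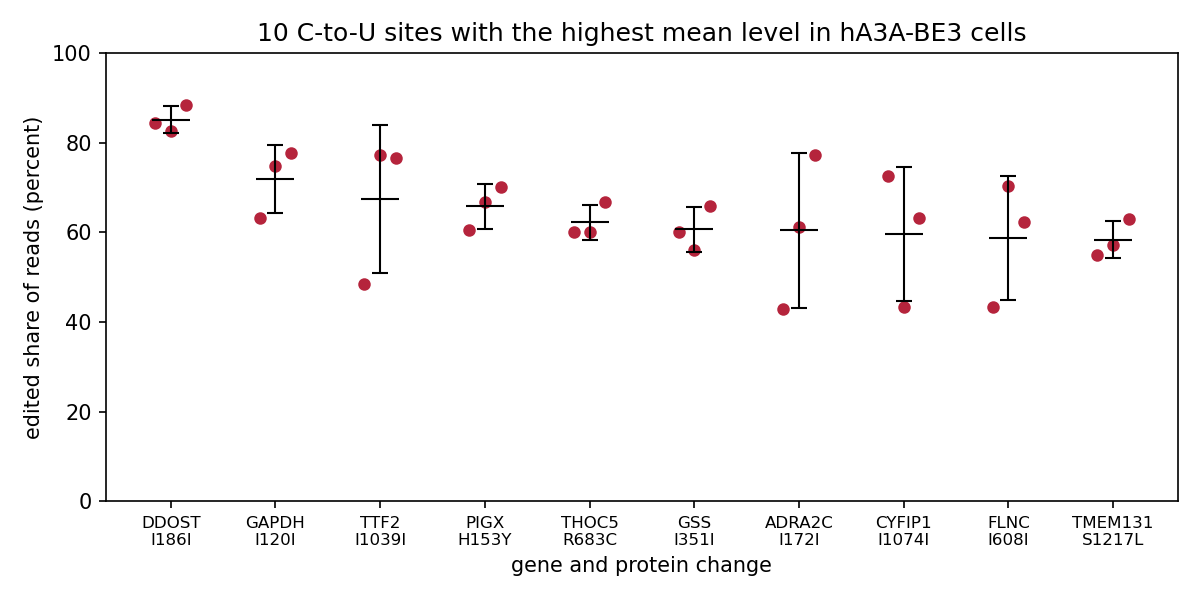
Edited share of reads in percent, from 0 to 100, at the 10 recurrent C-to-U sites with the highest mean level, at most 1 per gene, with a point per hA3A-BE3 library and a black bar for the mean ± SD (n = 3). DDOST I186I leads at 85.2% and TMEM131 S1217L is the lowest of the 10 at 58.4%.

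Over the whole C-to-U list of a library the median level was lower in hA3A-BE3 cells, 9.32% ± 0.515 (SD, n = 3), than in controls, 16.4% ± 2.12 (SD, n = 9; exact permutation p = 0.00909, adjusted p = 0.0418). The difference of -7.04 percentage points was -6.90 at sites with at least 50 covering reads, where the test no longer passed (exact permutation p = 0.455). With the sites of non-transfected cells left out it shrank to -0.54 (exact permutation p = 0.619). It was -3.91 with at least 20 covering reads, -11.7 at an edited fraction of at least 10% and -23.2 with at least 5 mutated reads (exact permutation p = 0.00909 for each). The median covering reads of C-to-U sites averaged 48.7 in hA3A-BE3 libraries and 28.5 in controls. A call needs at least 2 mutated reads, so lower levels can be called where more reads cover a site. How much this contributed to the difference was not tested.

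Nearly all edited cytosines of hA3A-BE3 cells stood after a U. Of exonic C-to-U sites, 95.9% ± 0.551 (SD, n = 3) had U at the preceding base, against 17.8% ± 6.91 (SD, n = 9) in controls (exact permutation p = 0.00909, adjusted p = 0.0418). Among 1043 exonic recurrent sites 1034 (99.1%) had this UpC. The base before it, at -2, was A at 59.5% of the recurrent sites, U at 22.4%, C at 14.7% and G at 3.36%, and the base at -3 was C at 69.2%. After the edited base, G stood at 48.8% and A at 40.5% of sites. At the 176 exonic C-to-U sites of the control libraries each base took between 19.9% and 27.3% at -1 and between 21.02% and 28.4% at -2. The bases beyond -1 were examined only after the data had been seen. Recurrent sites without a preceding U included DNAJB1 N143N, after an A, and the 3' UTR site of PSMD8 named below, after a G.

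**Figure D3:**
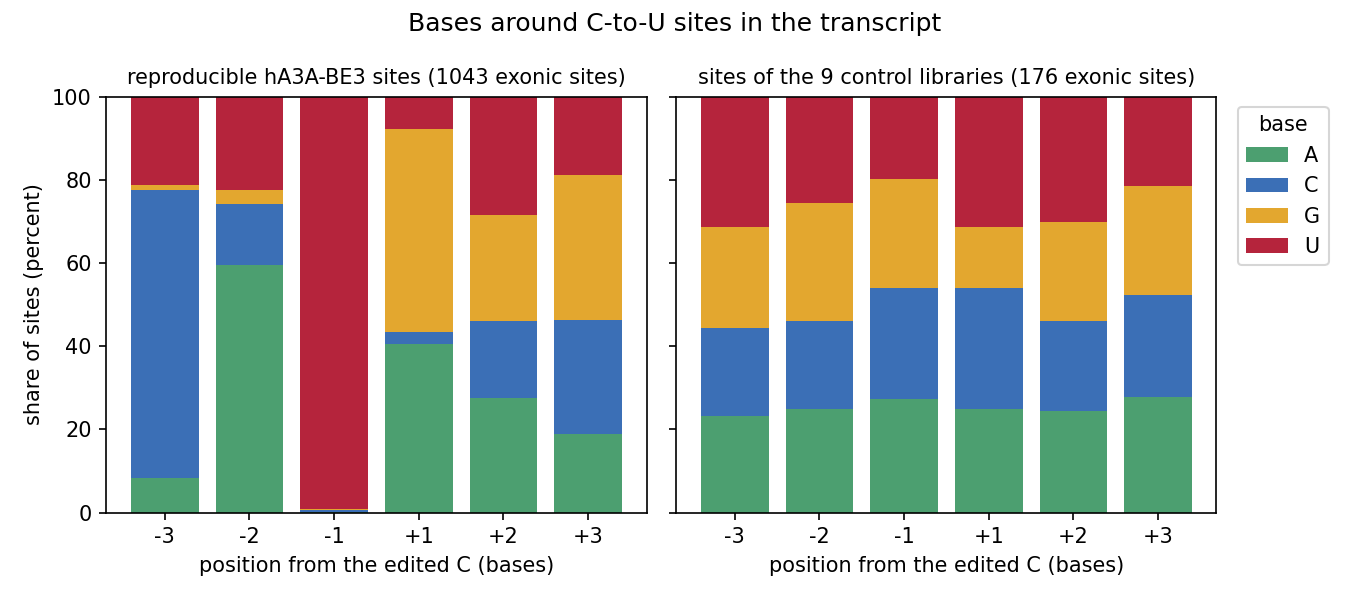
Share of sites in percent with each base at the 3 transcript positions before and after the edited C, for 1043 exonic recurrent hA3A-BE3 sites and 176 exonic C-to-U sites of the 9 control libraries. U fills 99.1% of position -1 in the hA3A-BE3 panel and 19.9% in the control panel.

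Coding sequence took most of the hA3A-BE3 sites. Per library, 69.99% ± 1.91 (SD, n = 3) of C-to-U sites were coding, against 40.0% ± 6.93 (SD, n = 9) in controls, and 1.10% ± 0.260 against 21.8% ± 4.11 were intronic. Non-coding exons held 0.793% against 4.66% and intergenic positions 0.589% against 5.07%. These 4 regions each gave an exact permutation p of 0.00909 and an adjusted p of 0.0136, while the 3' UTR share, 25.2% ± 1.86 against 24.8% ± 3.40, gave p = 1 and the 5' UTR share, 2.34% against 3.65%, p = 0.409 by the same test. With at least 50 covering reads 0 regions passed the adjusted threshold, and with any hA3A-BE3 library left out, 2 against 9 libraries brought none under it. Of the 1057 recurrent sites, 724 (68.5%) were coding, 289 (27.3%) lay in 3' UTRs and 22 (2.08%) in 5' UTRs. Of the coding sites 420 (58.0%) were synonymous, 225 (31.1%) changed an amino acid and 79 (10.9%) made a stop codon, and 295 (40.7%) left an isoleucine codon coding for isoleucine. The protein effects were tallied after the data had been seen.

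The excess of C-to-U sites ran through nearly every group of genes fixed before the data were examined. Of 20 lists, 18 held more C-to-U sites in hA3A-BE3 libraries than in controls at an adjusted p of 0.0101 (exact permutation test, every hA3A-BE3 library above every control). The exceptions were the mitochondrial genome, with 0.667 sites per hA3A-BE3 library and 0.778 per control (exact permutation p = 1), and blood cell markers, with no called site of any kind. The excess over all C-to-U sites was 92.8-fold, so these tests largely repeat it and single out no list. Even fibroblast markers, with 1 site per hA3A-BE3 library and 0 in controls, were among the 18. The excess of a list was not compared with that over all sites. In 5 lists the genes with a recurrent site were over-represented among genes with any called site, of which 15.7% (879 of 5608) had a recurrent site. They were cytoskeleton genes (13 of 32, odds ratio 3.72, Fisher's exact adjusted p = 0.0119), glycolysis (7 of 14, odds ratio 5.42, adjusted p = 0.0283), the proteasome (9 of 24, odds ratio 3.25, adjusted p = 0.0387), translation factors (10 of 28, odds ratio 3.01, adjusted p = 0.0387) and DNA repair (19 of 68, odds ratio 2.11, adjusted p = 0.0419). Against the narrower background of genes with a change other than C-to-U in at least 2 libraries, 0 lists passed and glycolysis had the smallest adjusted Fisher's exact p, 0.0623. There, on fewer genes, recurrent sites were found in 3 of 3 glycolysis genes, 1 of 3 of the proteasome (odds ratio 2.92), 2 of 8 translation factors (1.95), 4 of 17 DNA repair genes (1.81) and 0 of 3 cytoskeleton genes. Transcript length and abundance were not matched in either test.

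Cytoskeleton transcripts carried 65.0 ± 24.2 (SD, n = 3) C-to-U sites per hA3A-BE3 library and 0.111 per control. FLNA, the actin-crosslinking filamin, was led by F370F at 25.1% ± 12.04, the beta-actin gene ACTB by I34I at 21.2% ± 6.78 and MYH9, a non-muscle myosin heavy chain, by I394I at 11.3% ± 4.74. Glycolysis genes carried 17.7 ± 6.51 sites against 0.333, with ENO1, an enolase, at 42.8% ± 7.28 (I284I) and the pyruvate kinase PKM at 10.5% ± 2.94 (F12F) beside GAPDH. Proteasome genes carried 21.3 ± 9.29 against 0, with PSMA7 I133I at 38.0% ± 8.51, PSMD11 I242I at 27.5% ± 9.22 and a 3' UTR site of PSMD8 at 10.8% ± 0.847. Translation factors carried 22.3 ± 7.51 against 0, with EIF2B1 I301I at 28.7% ± 15.4, EIF3B L810L at 16.04% ± 4.98 and a 3' UTR site of EIF3L at 14.7% ± 3.46. DNA repair genes carried 73.0 ± 26.2 against 0.222, with RFC2, a subunit of the clamp loader, at 26.2% ± 8.66 (I221I) and PRKDC, the catalytic subunit of DNA-dependent protein kinase, at 13.9% ± 4.54 (F1060F) beside DDB1.

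Chaperone transcripts held 38.3 ± 16.5 sites per hA3A-BE3 library against 0.111 per control. DNAJB1 N143N lay at 24.3% ± 3.97, CCT5, a subunit of the chaperonin, at 46.6% ± 7.40 (I335I) and a 3' UTR site of the mitochondrial chaperone HSPA9 at 11.9% ± 2.36. Splicing factors held 41.3 ± 17.2 against 0.111, with SF3A1 I764I at 27.2% ± 10.9, PTBP1 S319L at 18.9% ± 2.01 and SNRNP200 I586I at 9.32% ± 1.66. Cell cycle genes held 44.7 ± 16.9 against 0, among them the replication licensing genes MCM7 (R224C, 28.0% ± 7.44) and MCM6 (R387X, 13.3% ± 1.61) and the phosphatase CDC25A (F197F, 22.1% ± 5.84). Nuclear genes of oxidative phosphorylation held 27.3 ± 10.8 against 0, with a 5' UTR site of COX5A at 23.0% ± 6.30, NDUFB5 R26C at 16.6% ± 2.03 and a 3' UTR site of COX7A2 at 9.42% ± 2.57. Ribosomal protein genes held 15.3 ± 4.04 against 0, with 3' UTR sites of RPS16 at 17.7% ± 6.36 and RPL37 at 10.1% ± 2.57 (SD, n = 3 throughout). For these 5 lists the share of genes with a recurrent site gave adjusted Fisher's exact p-values of 0.055, 0.114, 0.0536, 0.0536 and 1.

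Tumour suppressor transcripts held 68.7 ± 36.5 C-to-U sites per hA3A-BE3 library and 0.889 per control. SMAD4, a mediator of TGF-beta signalling, carried S171L at 50.9% ± 6.36, TSC2, a restraint on mTOR signalling, I383I at 37.5% ± 13.9, and the chromatin remodeller PBRM1 R146X at 21.8% ± 5.30. Oncogenes held 33.7 ± 15.4 against 0.444, with a 3' UTR site of RAC1 at 29.03% ± 5.47, IDH2 I392I at 22.8% ± 6.25 and a 5' UTR site of MDM2 at 13.3% ± 1.95. Polycomb genes held 17 ± 6.56 against 0, with PCGF3 R123W at 37.2% ± 5.84, L3MBTL2 S524L at 36.6% ± 8.56 and MGA R134C at 9.69% ± 5.74. Histone genes held 5.33 ± 2.52 against 0.778, with an intronic site of H2AFV at 20.7% ± 6.03 and H1F0 S46L at 7.70% ± 2.97. Both reported APOBEC3A RNA targets on the list carried recurrent sites, DDOST and the succinate dehydrogenase gene SDHB, whose stop codon R46X lay at 18.1% ± 4.60. The list of ADAR recoding targets held 24 ± 13 C-to-U sites against 0, with CYFIP2 I613I at 17.7% ± 5.46 and a 3' UTR site of ADAR itself at 10.9% ± 1.33 beside FLNA. Interferon response genes held 5 ± 3.61 against 0.111 and had ADAR as their single gene with a recurrent site. Fibroblast markers held 1 site in each hA3A-BE3 library and 0 in controls, none of them recurrent. Adjusted Fisher's exact p-values for these 8 lists were 0.115, 0.845, 0.26, 0.197, 0.055, 0.564, 1 and 1.

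PE3 cells carried about as many C-to-U sites as control cells. The PE3 libraries held 43 and 44, a mean of 43.5 ± 0.707 (SD, n = 2), against 46.0 ± 3.20 (SD, n = 9) in controls, a log2 difference of -0.08 (two-sided exact permutation p = 0.327, adjusted p = 0.443). The 95% interval of the fold ran from 0.816 to 1.05, and 2 against 9 libraries can give p-values down to 0.0364. Per Gb of mapped bases the difference turned direction, to 0.41 on the log2 scale (exact permutation p = 0.327). This rested on PE3 replicate 2, with 13.2 sites per Gb, since replicate 3 had 5.79 and controls a mean of 6.45. With at least 5 mutated reads per site the difference kept the direction of the main setting and grew to -0.64 (exact permutation p = 0.0364, adjusted p = 0.105). The median C-to-U site had 16 covering reads in PE3 replicate 2 and 30.5 in replicate 3, against a mean of 28.5 in controls. Whether the low coverage of replicate 2 set this drop was not tested. Against hA3A-BE3, whose libraries held 97.8 times as many, 3 against 2 libraries gave an exact permutation p of 0.2, the smallest possible. C-to-U sites made up 2.87% ± 1.45 (SD, n = 2) of the PE3 lists and 2.01% ± 0.463 of the control lists (exact permutation p = 0.182), the UpC share was 22.6% ± 7.77 against 17.8% ± 6.91 (p = 0.473 by the same test), and the median level 16.8% ± 6.05 against 16.4% ± 2.12 (exact permutation p = 0.8). In that order PE3 replicate 2 had 3.90%, 28.1% and 21.1%. Replicate 3 had 1.85%, 17.1% and 12.5%, each below the control mean. Coding sequence held 50.6% ± 0.822 of the PE3 C-to-U sites against 40.0% ± 6.93 in controls (exact permutation p = 0.0364, adjusted p = 0.218). Of the 20 gene lists, 0 differed between PE3 and controls by the exact permutation test, adjusted or not. The lists held too few sites for these tests to decide whether PE3 changed any of them. Splicing factors, translation factors, ribosomal proteins, oncogenes, cell cycle genes and histones had 1 C-to-U site in 1 of the PE3 libraries and 0 in the other, and the other 14 lists had 0 in both.

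In the targeted gene RNF2, which encodes a catalytic subunit of a Polycomb complex, a site was called in both PE3 libraries and in none of the other 12. It was a G-to-A change on chromosome 1, position 185087640 (GRCh38, plus strand, coding exon), synonymous as Q29Q. An edit written into the DNA of the target would also appear in its RNA. The lists cannot tell such an edit from a change made in RNA. In PE3 replicate 2, 9 of 9 covering reads carried A (100%, exact 95% interval 66.4 to 100), and in replicate 3 it was 8 of 13 (61.5%, exact 95% interval 31.6 to 86.1). These intervals cover counting error only. The larger read depth at this site was 23 and 52 reads, and the bases of the reads outside the 9 and 13 are not known here. A further 6 sites, all A-to-I, were called in both PE3 libraries and no other. Pairs of libraries of a control group shared a mean of 57 sites absent from the other groups in non-transfected cells, 43 in EGFP and 24.7 in Cas9 cells, where the lowest pair had 7. The 6 PE3 sites lay in introns of HNRNPC, PVT1, TAF2 and LINC02001 and in the 3' UTR of TSNAX, with 2 to 6 mutated reads each. HNRNPC led with 5 of 10 reads (exact 95% interval 18.7% to 81.3%) in replicate 2 and 2 of 15 (1.66% to 40.5%) in replicate 3. By the same rule, non-transfected cells were led by SFXN2 (3' UTR, mean 67.4%), DAP3 (intron, 65.0%) and LYRM7 (3' UTR, 60.3%), and EGFP cells by POLA1 (intron, 26.3%), an intergenic site (18.5%) and RCC1 (intron, 14.6%).

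A-to-I sites, the product of the cells' own ADAR enzymes, were the most frequent change outside the hA3A-BE3 group. Controls held 2116 ± 542 (SD, n = 9), hA3A-BE3 libraries 2150 ± 309 (SD, n = 3) and PE3 libraries 867 and 2136. The log2 difference from controls was 0.06 for hA3A-BE3 (exact permutation p = 0.9, 95% interval of the fold 0.742 to 1.56) and -0.59 for PE3 (exact permutation p = 0.255, 0.297 to 1.67). The PE3 value rested on replicate 2, the library with the fewest mapped bases: without it the log2 difference was 0.06. At the 138 A-to-I sites called in all 14 libraries the mean level was 36.6% ± 1.22 in hA3A-BE3 cells and 36.3% ± 1.99 in controls (exact permutation p = 0.836), and 39.8% ± 2.18 (SD, n = 2) in PE3 cells (exact permutation p = 0.0727, adjusted p = 0.228). PE3 replicate 2 stood at 41.3% and replicate 3 at 38.2%, against 33.7% to 39.3% in controls. A call needs at least 2 mutated reads, so where few reads cover a site only higher levels are called. The median site of PE3 replicate 2 had 11 covering reads, and whether this raised its level was not tested. In controls 59.4% ± 3.97 (SD, n = 9) of A-to-I sites lay in 3' UTRs and 26.2% ± 4.39 in introns, and no region differed in either editor group at an adjusted p under 0.05 (exact permutation test). For PE3 this says little, since 2 against 9 libraries give no exact permutation p under 0.0364. The coding share of PE3 C-to-U sites, at that p, adjusted to 0.218. The share in non-coding exons of hA3A-BE3 cells, 4.29% against 3.51%, had an unadjusted p of 0.0273.

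Among ADAR recoding targets, the DNA glycosylase gene NEIL1 had an intronic site (chromosome 15, position 75353280) called in all 14 libraries at 35.6% ± 8.05 (SD, n = 14), over 6 to 45 reads. Its group means were 23.5% in non-transfected, 36.3% in EGFP, 42.8% in Cas9, 34.7% in PE3 and 40.4% in hA3A-BE3 cells. BLCAP had Y2C called in 3 libraries at 20.4% ± 7.63 (SD, n = 3). CDK13, COG3 and SON each had a site called in 1 library.

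The 10 other base changes numbered 276 ± 45.6 (SD, n = 3) in hA3A-BE3 cells, 198 ± 8.49 (SD, n = 2) in PE3 cells and 233 ± 36.2 (SD, n = 9) in controls (exact permutation p = 0.1 and p = 0.109). The hA3A-BE3 difference of 0.25 on the log2 scale became 0.31 with exact permutation p = 0.0121 without Cas9 replicate 3, and kept 0.25 with p = 0.0312 in the paired analysis by replicate block. It shrank to 0.019 with at least 5 mutated reads (exact permutation p = 0.873), to 0.068 at an edited fraction of at least 10% (exact permutation p = 0.482) and to 0.12 without hA3A-BE3 replicate 3 (exact permutation p = 0.4). With each of the 12 changes tested in both editor groups, 4 of 24 exact permutation tests had an unadjusted p under 0.05 and 0 an adjusted one. Those 4 were C-to-U, G-to-A (84.3 ± 10.599 against 66.6 ± 7.89, p = 0.0182) and C-to-G (10.3 ± 3.21 against 6.56 ± 1.67, p = 0.0455) in hA3A-BE3 cells and A-to-U (9.50 ± 0.707 against 7.11 ± 1.17, p = 0.0364) in PE3 cells, each by the exact permutation test. The C-to-U test, alone at the smallest exact permutation p of 3 against 9 libraries, 0.00909, adjusted to 0.218 over the 24. Total called sites were 7112 ± 2305 in hA3A-BE3 cells and 2394 ± 569 in controls (log2 1.55, exact permutation p = 0.00909, adjusted p = 0.0418), and 1743 ± 907 in PE3 cells (exact permutation p = 0.255). Over 23 alternatives the adjusted exact permutation p of the hA3A-BE3 total ran from 0.0418 to 0.167 and was under 0.05 in 9.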

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

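The tests of mapped depth and of calling sensitivity were chosen after the results were seen, and the tests of editing level, exonic sites, neighbouring sites and recurrence before. Among the 9 control libraries, Cas9 replicate 3 stood apart from the others in the number of changes other than C-to-U and A-to-I, 322 against 238 in the nearest, and in T-to-C sites, 166 against 97 in the nearest. Chance sets a library apart in about 1 of 20 such measures, and 18 were examined. T-to-C is itself among the other changes, so these flags are not separate. It made up 166 of the 322 in Cas9 replicate 3. It made up 92 of the 238 in the nearest control, non-transfected replicate 2, and 70 of the 226 in Cas9 replicate 2.

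Cas9 replicate 3 had the most mapped bases, and T-to-C sites were called in every library, so depth and the origin of these sites were weighed. Per Gb of mapped bases its other changes lay inside the range of the other 8 controls (30.3 against 26.5 to 41.5, a gap of 0). Its T-to-C sites still ranked first (15.6 against 6.79 to 13.6). Their gap to the nearest control was 0.233 of the range, under the critical value for 9 libraries. This scaling takes sites to rise in proportion to mapped bases. Cas9 replicate 2 had fewer mapped bases than Cas9 replicate 1 but more sites of both kinds. Dividing by mapped bases lowers the deepest library most, so these values cannot decide whether depth set it apart. Errors that recur no more than transversions are argued against as the whole source of T-to-C sites: 24.2% were in 2 or more libraries (exact 95% interval 21.2 to 27.5), against 17.4% of transversions (14.6 to 20.5), although G-to-A sites, at 20.4% (17.3 to 23.9), overlap. A candidate explanation is A-to-I editing on the strand opposite to the assigned one: 45.6% of T-to-C sites lay within 50 bases of another, against 9.03% of G-to-A sites and 81.9% of A-to-I sites. Variants of the cell line stay open, and no biological explanation was tested.

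The number of C-to-U sites differed 2.58-fold between the hA3A-BE3 libraries, with replicate 1 lowest. Depth does not account for it, since sites per Gb of mapped bases still differed 2.53-fold (95% counting interval 2.41 to 2.65). Replicates 2 and 3 held 1.17 times the A-to-I sites of replicate 1 and 2.31 times its C-to-U sites. A yield of calls lowered equally for both changes therefore does not account for it either. The A-to-I sites called in all libraries had higher levels than most C-to-U sites of these cells. A-to-I numbers thus cannot decide whether replicate 1 lost calls mainly at low levels. At the 1072 C-to-U sites called in all 3, the edited share was lower in replicate 1 than the mean of the others at 81.3% of sites (exact 95% interval 78.9 to 83.6), with medians of 10.7%, 15.6% and 15.2% in replicates 1, 2 and 3. A lower editing level in replicate 1 may therefore have moved sites under the calling limits. The amount of editor per cell was not measured here, and no biological explanation was tested.

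A-to-I sites differed 2.29-fold between the 9 control libraries. Depth alone is argued against, since sites per Gb of mapped bases still differed 1.93-fold (95% counting interval 1.81 to 2.05). A lower share of intronic RNA in the libraries with few sites cannot be told apart from other causes: exonic sites per Gb of mapped bases ran from 144 to 228, a 1.58-fold range whose counting interval, 1.46 to 1.71, includes the limit of 1.5 set beforehand. The control group itself stays open as an untested biological difference.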

How the results depend on the processing

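Scaling to mapped bases was chosen after the data were seen; the other alternatives were set before. The C-to-U excess of hA3A-BE3 over controls kept its direction and its side of the unadjusted threshold of 0.05 in all alternatives, with exact permutation p-values of 0.00909 to 0.0364, as did its C-to-U share and UpC share. Adjusted over the comparisons, the excess stayed under 0.05 in 11 of 25 alternatives and the shares in 7 of 21. For all 3 the adjusted p was 0.0418 in the main setting, 0.0558 without most single controls, 0.0523 with at least 50 covering reads, 0.113 with the sites of non-transfected cells left out, 0.12 with the replicate block and 0.167 without a hA3A-BE3 library, where fewer libraries raise the smallest possible p. Sides of the threshold below are unadjusted. The cause of each change below was not tested unless stated. Differences are given as the first group minus the second, in log2 for numbers of sites and in percentage points for shares and levels. With at least 20 covering reads the PE3 level was -1.73 and the PE3 UpC share -1.30. With at least 50, the C-to-U sites of PE3 were 0.019 against non-transfected cells and 0.49 against EGFP, A-to-I sites of hA3A-BE3 -0.16, the hA3A-BE3 level -6.90 (no longer past the threshold), the PE3 level -0.73 and the PE3 level at shared A-to-I sites 4.40 (exact permutation p = 0.0364, over a range of 0.0364 to 0.4, and on 9 shared sites instead of 138), while 530 recurrent sites and 0 regions passed. With an edited fraction of at least 10%, C-to-U sites of PE3 were 0.022 against controls, 0.063 against non-transfected cells and 0.053 against Cas9, the PE3 level was -5.61 and 497 sites recurred. With at least 5 mutated reads, PE3 passed the unadjusted threshold (exact permutation p = 0.0364) for C-to-U sites (-0.64), other changes (-0.47) and level (8.97), and 676 sites recurred. With the sites of non-transfected cells left out, C-to-U sites of PE3 were 0.32 against controls, 0.41 against EGFP and 0.23 against Cas9, and the hA3A-BE3 level was -0.54; this setting gives no value for contrasts with non-transfected cells or for shared A-to-I sites. Without mitochondrial sites, C-to-U sites of PE3 against non-transfected cells were 0.0064 and the PE3 level -0.067.

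Per 1000 A-to-I sites, C-to-U sites of PE3 were 0.50 against controls, 0.58 against non-transfected cells, 0.67 against EGFP and 0.24 against Cas9. Per 1000 other changes they were 0.14, 0.14, 0.11 and 0.17 in that order, and per Gb of mapped bases 0.41, 0.40, 0.39 and 0.43, with total sites of PE3 at 0.0036 and other changes at 0.30. Scaled values were also taken as log2(value + 1). Counting sites called in at least 2 hA3A-BE3 libraries gave 2610 recurrent sites, by construction more. The narrower background left 0 of 5 enriched lists, with fewer genes tested.

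Leaving out a library at a time gave these ranges: C-to-U sites of PE3 against non-transfected cells -0.063 to 0.00073, total sites of PE3 -1.08 to 0.032, A-to-I sites of hA3A-BE3 -0.055 to 0.13 and of PE3 -1.24 to 0.059, other changes of hA3A-BE3 0.12 to 0.33, C-to-U share of PE3 -0.166 to 1.89, level of PE3 -3.86 to 4.70, UpC share of PE3 -0.628 to 10.4, level at shared A-to-I sites of hA3A-BE3 -0.191 to 0.94 and of PE3 1.91 to 5.0, passing without EGFP replicate 1 (3.83, exact permutation p = 0.0444). Without PE3 replicate 2 the lower or upper end was reached in most PE3 ranges. Recurrent sites ran from 1221 to 2103, and regions from 0 to 4, with 0 where a hA3A-BE3 library was left out and no p under 0.0364 was possible. The labels do not say that replicate numbers mark shared cultures or days, and same-numbered libraries did not deviate together (median correlation 0.017, from -0.17 to 0.16, against -0.016 for other numbers), and non-transfected replicate 1 correlated best with another number. With the replicate block the C-to-U excess of hA3A-BE3 was 6.54 (exact permutation p = 0.0312), and the 1 changed call was other changes of hA3A-BE3, at 0.25 with p = 0.0312. Of the tested values under alternatives, 421 kept direction and side of the unadjusted threshold, 43 turned direction, 7 came to pass it and 2 no longer passed. Of the numbers without a test, 53 stayed within 1.5-fold and 10 did not. PE3 has 2 libraries, and replicate 2 had 3.26 Gb of mapped bases.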

Other observations

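The test of the hairpin share, the level difference, the coding share and the splits of libraries were set before their results were seen; other loop shapes, matching on the base at -3, the sharing of C-to-U sites and the tally of the highest sites were chosen after. Many recurrent hA3A-BE3 sites could fold into a short hairpin with the edited C near the end of its loop. Of 1034 recurrent UpC sites, 224 (21.7%, exact 95% interval 19.2 to 24.3) had the C as the last base of a 4-base loop closed by a stem of at least 4 pairs, counting G-U pairs. Among 224612 UpC cytosines of the same transcripts that were called in no library the share was 2.02% when matched on the base at -2, and 1.82% when matched on the bases at -2 and -3. The C as the last base of a 3-base loop was found at 14.8% of the recurrent sites against 1.95%, and as the fourth base of a 5-base loop at 18.4% against 2.21%, whereas the first base of a 4-base loop gave 2.42% against 2.57%. In a 6-base loop the fifth base gave 14.2% against 2.15% and the fourth 5.42% against 2.19%, while the last base gave 2.51% against 2.19% in 5-base and 1.45% against 2.14% in 6-base loops. A single site can count under several loop sizes. Recurrent sites in a 4-base loop had a median level of 16.01%, those without one 13.4%, a difference of 2.65 percentage points (permutation p = 0.00011 over 100000 permutations of sites, which are not replicates), and 12 of the 20 highest UpC sites had such a loop. A preference of the editor for cytosines toward the 3' end of small loops, at a place that depends on loop size, is a hypothesis consistent with these shares; structures in the cell were not measured here.

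Coding sequence held 69.9% of the 1026 recurrent UpC sites in mRNAs (exact 95% interval 67.0 to 72.7) and 46.7% of the 223596 uncalled UpC cytosines of the same transcripts, a difference of 23.2 percentage points. By base at -2 the shares were 73.5% against 53.1% for A and 54.1% against 46.3% for C. They were 74.3% against 47.7% for G and 69.8% against 41.8% for U. Each called site was placed in a transcript where it was coding if any allowed it, and uncalled cytosines were classed in those transcripts. The uncalled cytosines were pooled, so transcripts with many of them weigh more. The comparison therefore cannot decide whether the position of UpC cytosines accounts for the coding share. Uneven coverage along transcripts could contribute and was not tested.

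Of the splits of the 3 hA3A-BE3 and 9 control libraries into 3 and 9, 100 were drawn with the real split included, and 1, the real split, had as many as 18 gene lists with more C-to-U sites. The highest other split had 0. In each of the 18 lists every hA3A-BE3 library lay above every control, so this number follows from the exact tests of the lists and adds no separate evidence.

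Some C-to-U sites of cells without the base editor were also called in hA3A-BE3 libraries. The hA3A-BE3 sites were taken here without requiring their absence from other groups. Positions that recur across groups count among them, so sharing is no sign of editor activity in other cells. In the 9 control libraries 13 to 18 of the 42 to 53 C-to-U sites were among the 2633 sites called in 2 or more hA3A-BE3 libraries. In the PE3 libraries it was 9 and 11, a mean of 10.0 against 15.7 in controls, and 31 and 27 of their C-to-U sites were in no other library outside the hA3A-BE3 group, a mean of 29 against 20.1 in controls (exact permutation p = 0.0364 for both, the smallest that 2 against 9 can give, before any correction). A PE3 library had fewer libraries of its own group to share sites with than a control library had. PE3 replicate 2 also had the fewest mapped bases. How far group size and depth set these numbers was not tested, so they do not show changes made by PE3.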
